A study of Rattus norvegicus with 5 samples.

How the data were processed

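RNA from 6 preparations was pooled within each of 5 groups, per the labels' protocols: PC12 cells with vehicle, PC12 cells with 1 mM or 6 mM sodium butyrate for 48 h, and adrenal medulla of saline-injected and butyrate-injected rats. Biotin-labelled cRNA from 6 µg total RNA was hybridised to 1 array per pool, per the labels' protocols. Groups were taken from the sample titles and descriptions.

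The authors deposited an intensity (the MAS 5 signal, on a linear scale), a detection call and a detection p-value per probe set and array, in tables whose columns follow the layout of Affymetrix expression software, per the file headers. The software version and the target of the scaling are not given in the sources used here. From the values, the mean of the middle 96% of the deposited signals was 500 on every array. The authors' deposited comparison tables also give a log2 ratio to 1 decimal, a change call (the other kind of call, Increase, Decrease, marginal forms of both, or no change) and a change p-value, with control relative to treated, and these were turned so that a positive value means higher with butyrate. The authors' deposited fold sheets hold a signed fold, treated over control, and were used only to check that direction. In the fold sheet of the 6 mM comparison, 1 line was empty in the copy used here, and it is not reported. The series-wide table of deposited intensity values differed from the signals of the comparison tables by at most 0.1. No interval of the authors' log ratio was used.

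Log2 ratios were computed from the deposited signals as the authors scaled them. A listed 0 was set to 0.1 before the log, a step chosen after the files were opened, which concerned 1 probe set on the PC12 control array. A probe set was called when the size of the log2 ratio was at least 1 and the array with the higher signal was Present, and control probe sets were left out. With 1 array per group, no p-value was computed, and the calls describe these arrays. Where the dimmer array was called Absent, a fold is given as at least the brighter signal over the higher of the dimmer signal and the floor of its array, the 75th percentile of the signals of Absent probe sets, which was 31.4 to 58.6. The median signal of an array was 116.3 to 167.0 and the highest 24213.5 to 31927.3.

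Of the probe sets for transcripts, 20826 named 1 gene in the platform annotation, 436 named several and 9780 named none, and a name was given only where there was 1. They stood for 14217 genes. Symbols were compared with a RefSeq gene table of the assembly GRCr8, used only for names, and none had to be updated among the 20758 probe sets whose gene identifier it held. The probe set with the highest mean log2 signal over the arrays stood for a gene. The other probe sets of called genes pointed the same way in 95.5% of cases at 6 mM, 97.3% at 1 mM, 96.1% between the doses and 93.7% in the adrenal medulla.

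Before the data were examined, 34 gene lists with 856 symbols were fixed, of which 727 genes were found on the array. A gene was measured when Present on at least 1 of the 2 arrays. The median log2 ratio of a list was given as a percentile among 10000 random lists of the same size, matched on mean signal over 20 bins, and a list stood apart when that percentile lay outside the central 95%. A list with fewer than 3 measured genes got no percentile. With 34 lists and 4 comparisons, some lists stand apart by chance. Named genes were chosen by a rule fixed at the same time: the 12 highest and 12 lowest genes of each comparison by floored log2 ratio, with the authors' change call in the same direction where a deposited table gives one, up to 4 called members with the largest ratios of each list described, and Th, Dbh, Pnmt, Penk, Npy, Chga, H1f0, Cdkn1a, Ccnd1 and Star whatever their values. No probe set named H1f0.

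Overlaps of calls between comparisons were set against independent lists of the same sizes. Because both PC12 doses used the same control array, 100 pairs of arrays without an effect were simulated from the control signals. Only probe sets Present on the control array could be called in them. The noise SD per signal bin was 0.15 to 1.27 on the log2 scale, estimated from the ratios between 1 mM and control themselves. It was taken from the median absolute deviation of each bin, which discounts extreme ratios, whether these are real effects of 1 mM or noise. Whether it overstates or understates the array noise was not shown. The calling step was tested on simulated data over 31042 probe sets. At 4-fold, 98 of 100 planted genes were recovered for the 6 mM comparison, 97 for 1 mM and 99 for the adrenal medulla, and at 8-fold 100 of 100 in each. Among unchanged probe sets, 434 of 18192, 418 of 18192 and 698 of 19517 were called. These were probe sets Present on the control array, whose detection calls were copied to the treated array. Calls on probe sets Absent in control were thus not tested. The noise came from the ratios of 1 mM to control in every comparison, so the adrenal count reflects the noise of PC12 arrays. A planted list shift of 0.5 reached percentile 100 in each, and 15, 8 and 12 of 200 lists without a shift fell outside the central 95%. The simulated noise was independent between probe sets and these lists were drawn at random. The counts therefore do not cover lists of genes that vary together.

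The alternatives tried were the authors' deposited log2 ratio, their change call as a further condition, quantile normalization over the 5 arrays, centring on the median, Present on both arrays, no detection filter, floored signals, the series-wide table, thresholds of 1.5-fold and 3-fold, the mean over all probe sets of a gene, and random lists without matching. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.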

Results

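Gene expression was measured on 5 Affymetrix rat expression arrays, each reading 31042 probe sets for rat transcripts beside 57 control probe sets. Butyrate is a short-chain fatty acid made by gut bacteria from fibre and is an inhibitor of histone deacetylases. PC12 cells, a line derived from a rat tumour of adrenal chromaffin cells that makes and releases catecholamines, were given vehicle, or 1 mM or 6 mM sodium butyrate for 48 h. Male Sprague-Dawley rats were injected 3 times, 12 h apart, with saline or with 500 mg/kg sodium butyrate, and the adrenal medulla, the catecholamine-secreting core of the gland, was taken 2 h after the last injection. The stated purpose was to find which gene networks respond to short-chain fatty acids at each dose in PC12 cells, and whether the sympathoadrenal system of the animal responds in a similar way. RNA of 6 preparations was pooled within each group and read on 1 array, so there was no replicate, no test was possible, and the number of arrays limits the precision of every value. A probe set was called higher or lower when its signal differed at least 2-fold and the array with the higher signal had the detection call Present. Between 58.9% and 63.9% of the probe sets were Present on an array, and the mean of the middle 96% of the signals was 500 on all 5.

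PC12 cells at 6 mM differed from control cells in a large part of what they express. Genes of DNA replication and mitosis were lower almost throughout, some by 20-fold or more, and most chromaffin markers were lower too. Of the immediate early genes, 15 of 29 were higher. Of 19878 probe sets Present on at least 1 of the 2 arrays, 2535 were higher and 2320 were lower, together 24.4%. Among the higher ones, 894 were called Absent in control cells. The higher calls outnumbered the lower ones on the deposited scale but not after quantile normalization, where their share was 47.6% instead of 52.2%.

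Of 59 measured genes of S phase and mitosis, 54 were lower at 6 mM, 1 was higher and 4 were neither, with a median log2 ratio of -3.41, below all 10000 random lists of genes with matched signals. Mki67, a marker of proliferating cells, had a signal of 4097 in control cells and 48.1, called Absent, at 6 mM, at least 85.2-fold lower. Top2a, the topoisomerase of dividing cells, was at least 54.6-fold lower. The cyclin gene Ccna2 was 52.0-fold lower, and the mitotic cyclin gene Ccnb2 was at least 45.6-fold lower. Pclaf, which encodes a partner of the replication clamp, was at least 143-fold lower and had the largest floored ratio among the lower genes. Ect2, needed for cytokinesis, was 82.0-fold lower, and Ube2c, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, was at least 51.5-fold lower. The mitotic kinesin gene Kif18b and the kinetochore gene Knstrn were at least 50.6-fold and at least 48.6-fold lower. Cell cycle inhibitors and growth arrest genes lay above the random lists with a median of 0.58, but their calls were split into 5 higher, 5 lower and 10 neither. Cdkn1c, the p57 inhibitor, was 3.66-fold higher, whereas Cdkn1b, the p27 inhibitor, was 3.97-fold lower and Rbl1, a relative of the retinoblastoma gene, was 4.01-fold lower. Tp53inp1, a target of p53, was at least 4.09-fold higher. Cdkn1a, the p21 inhibitor often induced by deacetylase inhibitors, read 1251.5 in control cells and 1921 at 6 mM on its brighter probe set, below the size rule at a log2 ratio of 0.62. A dimmer probe set of Cdkn1a gave 2.01. Ccnd1, the G1 cyclin, was 3.70-fold lower.

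Of 14 measured chromaffin markers, 10 were lower at 6 mM and none was higher, with a median of -1.55. Of 12 genes of catecholamine synthesis, storage and breakdown, 6 were lower, 3 were higher and 3 were neither, with a median of -1.08, a list that moved inside the random lists when Present was required on both arrays. Th, the rate-limiting enzyme of catecholamine synthesis, read 20076 in control cells, near the top of the range, where ratios may be compressed, and 2840 at 6 mM, 7.07-fold lower. Dbh, which makes noradrenaline from dopamine, was at least 12.6-fold lower, and Slc18a1, the vesicular monoamine transporter of chromaffin granules, was at least 82.6-fold lower. Cyb561, which supplies electrons to Dbh in the granule, was 5.23-fold lower. Pnmt, which makes adrenaline, and Penk, the enkephalin precursor, were Absent on all 3 PC12 arrays.

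Of 15 neuropeptide and secretory granule genes, 5 were lower, 2 were higher and 8 were neither, with a median of -0.28, inside the random lists when these were not matched on signal. The granule proteins Chga and Chgb were 3.04-fold and 2.88-fold lower, and the vasodilator peptide gene Adm was 3.56-fold lower, but Npy, the sympathetic co-transmitter, was 4.69-fold higher. Of 22 exocytosis genes, 9 were lower, 6 were higher and 7 were neither, with a median of -0.64, inside the random lists without the detection filter. Cadps, a priming factor of dense-core vesicles, was 16.3-fold lower, whereas the vesicle GTPase gene Rab3a and the vesicle protein gene Sv2b were 7.47-fold and 5.84-fold higher. Of 20 genes of neurite outgrowth and the neuronal cytoskeleton, 6 were lower, 4 were higher and 10 were neither, with a median of -0.57. Here the light neurofilament gene Nefl was 13.4-fold higher and the dendritic microtubule gene Map2 was 5.94-fold higher, while Dpysl3 and the neuronal intermediate filament gene Prph were 7.05-fold and 6.09-fold lower. Of 9 receptors of chromaffin cells, 4 were lower and none was higher, with a median of -0.73. Adora2a, the adenosine receptor, was 11.2-fold lower, P2rx2, an ATP-gated channel, was 8.96-fold lower, and Chrna3, the ganglionic nicotinic subunit, was 3.02-fold lower. The median of these receptors moved inside the random lists after quantile normalization.

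Of 29 immediate early and activity-regulated genes, 15 were higher, 3 were lower and 11 were neither at 6 mM, and their median of 1.01 lay above all random lists. Atf3, a stress-induced transcription factor, was at least 18.6-fold higher. Egr2 and Egr1 were 18.0-fold and 15.5-fold higher, but the control signal of Egr2, 24.2, lay below the background floor of 31.4. Klf2 was 9.07-fold higher, with 0.51 to 3.60 on the log2 scale on its other probe sets. Of 10 genes of matrix and transforming growth factor beta response, 5 were higher and 1 was lower, with a median of 0.97, inside the random lists with Present on both arrays. Fibronectin, Fn1, was 7.95-fold higher, although the authors' deposited table gave it no change call, and Igfbp5 was 6.27-fold higher. Genes of endoplasmic reticulum stress and the amino acid response lay below the random lists with a median of -0.59, and 8 of 29 were lower, 2 were higher and 19 were neither. The lower ones included Mthfd2 of mitochondrial folate metabolism, 4.67-fold, and Psph of serine synthesis, 3.27-fold, while the stress factor gene Ddit3 was 3.88-fold higher. Among 8 measured markers of white blood cells, 6 were higher and none was lower. Their median was 2.33, or 1.33 with dim signals set to the background floor, where the list was no longer outside the random lists. Nor was it with Present on both arrays or without the detection filter. They included Cd74, at least 7.12-fold higher, and the class II histocompatibility gene RT1-Ba, at least 6.81-fold higher, at signals of 223.7 and 213.9.

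The largest floored ratios at 6 mM among higher genes belonged to Crybb2, a crystallin of the eye lens, at least 78.6-fold higher, and to the collagen gene Col5a3, at least 66.8-fold higher. Ttyh2 was 27.3-fold higher, Fcrla, an Fc receptor relative of B cells, at least 24.0-fold, Tmsb4x, which binds actin monomers, 23.1-fold, Rnase4 at least 21.8-fold and Arxes1 at least 21.5-fold. Arrdc4, an arrestin relative, was 21.4-fold higher, Gpx8 at least 18.9-fold, the germ cell gene Tex101 at least 18.8-fold and the metalloproteinase gene Mmp17 18.5-fold. Outside the groups above, G0s2, an inhibitor of triglyceride lipase, was at least 84.4-fold lower and Tmem255b at least 52.9-fold lower. Txnip, a thioredoxin-binding protein, was 6.71-fold higher, the metallothionein genes Mt3 and Mt2A were 8.07-fold and 5.00-fold higher, and the linker histone relative H1f10 was 2.04-fold higher. The other 18 lists with at least 3 measured genes lay inside the central 95% of random lists. Of these, heat shock genes were near the edge, with 4 of 16 lower, none higher and a median of -0.26 at percentile 2.84. Oxidative stress genes were split at 6 mM, with 6 higher and 5 lower of 23, as were genes of cAMP signalling, with 5 and 5 of 26. Of 20 glycolysis genes, 1 was higher and 3 were lower, the latter including hexokinase 2, Hk2, 3.97-fold. Of the 12 lists that stood apart, 6 did so under every alternative run. In the authors' deposited table for this comparison, 4306 probe sets had a change of at least 2-fold, 2268 of them higher and 2038 lower with butyrate.

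At 1 mM, PC12 cells differed from control cells in far fewer probe sets, and most of these were higher. The highest floored ratios belonged to single genes such as Rgs5, Ggt1 and Aldh1a1, and 6 of 24 genes of oxidative stress and metallothioneins were higher. The catecholamine list lay above the random lists and the cell cycle list below them, with few members called. Of 19390 probe sets Present on at least 1 array, 747 were higher and 237 were lower, together 5.07%, and 367 of the higher ones were Absent in control cells. Of the calls on probe sets Present in control cells, 358 were higher and 237 were lower. Simulated arrays with no effect gave on average 205 lower calls and at most 247. Their noise was taken from the same ratios, may include effects of 1 mM and discounts extreme ratios. Whether the lower calls exceed array noise was therefore not shown.

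Rgs5, a regulator of G protein signalling, had the largest floored ratio at 1 mM, at least 60.8-fold higher, with a signal of 1909.5 against 24.5. Ggt1, which breaks down extracellular glutathione, was at least 14.8-fold higher, Aldh1a1, which makes retinoic acid, at least 10.0-fold, and the aldo-keto reductase gene Akr1b8 at least 8.68-fold. The lipid carrier genes Pltp and Apoc1 were at least 9.78-fold and 8.70-fold higher, and Hsd11b1, which regenerates active glucocorticoid, was 6.84-fold higher. Olfml2a, Tppp3, which binds tubulin, Selenbp1 and Tceal5 were at least 7.25-fold, 7.17-fold, 7.07-fold and 6.60-fold higher. Mt3, a metallothionein of neurons, was 6.60-fold higher. The lowest floored ratios were much smaller. Acyp2, an acylphosphatase, was 3.72-fold lower and Qpctl, a glutaminyl cyclase of the Golgi, at least 3.53-fold lower. Among genes of mitosis and the centromere were Pimreg 3.30-fold, Cenpe at least 2.79-fold, Cenpw 2.73-fold, the mitotic kinesin gene Kif20a 2.70-fold, Ccnb2 2.70-fold and Cenpp 2.62-fold lower. Also among the 12 lowest, Rhox9, a homeobox gene, ST7, Negr1, a neuronal adhesion gene, and H4f3 were 2.87-fold, 2.76-fold, 2.71-fold and 2.62-fold lower.

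The cell cycle list had a median of -0.38 at 1 mM, with 6 of 58 genes lower, 1 higher and 51 neither, and it lay below all random lists. The single higher member was Ccnd1, 3.19-fold higher at 5817 against 1826, with 1.70 and 1.61 on the log2 scale on its other probe sets. The inhibitors of the cell cycle had a median of -0.42 with none of 19 called. Cdkn1a read 1387.5 at 1 mM, a log2 ratio of 0.15, and its dimmer probe set gave 0.98. Catecholamine genes had a median of 0.45 with 2 of 12 higher, Ddc, which makes dopamine, 3.53-fold and Gchfr, a regulator of cofactor synthesis, 2.42-fold. Th read 22676 and Dbh 535.3, both within 1.13-fold of control, with the same limit for Th. The chromaffin markers had a median of 0.26, and none of 14 was called. Chga read 13095 at 1 mM, a log2 ratio of 0.38. Exocytosis genes had a median of 0.32 with 2 of 21 higher, Rab3b at least 3.53-fold and Sv2b 2.46-fold. Nicotinic and other receptors had a median of 0.77, and 2 of 9 were higher, Chrnb2 by 2.41-fold and Chrna5 by 2.04-fold, although the authors' deposited table gave Chrnb2 a log2 ratio of 0.5 and no change call.

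Of 25 immediate early genes, 5 were higher and 1 was lower at 1 mM, with a median of 0.37. They included Ier3, an early response gene, 3.44-fold, Egr1 2.79-fold, Myc 2.48-fold and Crem, a repressor of cAMP-driven transcription, 2.28-fold higher. Of 24 genes of oxidative stress and metallothioneins, 6 were higher and none was lower, with a median of 0.18. Gpx3, an extracellular glutathione peroxidase, was at least 3.34-fold higher, the glutathione transferase gene Gstp1 2.87-fold, and the haem oxygenase gene Hmox1 2.09-fold. Smaller group medians above the random lists were found for fatty acid oxidation, 0.22 with 2 of 30 higher including the dienoyl-CoA reductase gene Decr1 at 2.87-fold, and for glycolysis, 0.18 with 1 of 20 higher, Aldoc at 2.34-fold. Transport and sensing of short-chain fatty acids had a median of 0.31 with none of 4 called, and markers of Schwann cells had 0.60 with 1 of 4 higher. These lists were inside the random lists under 3 and under 2 of 9 alternatives. Histone deacetylases, acetyltransferases and readers had a median of -0.17 with none of 29 called, a list that was inside the random lists under 5 of 9 alternatives. Npy was 2.56-fold higher. Of the 13 lists that stood apart, 10 did so under every alternative run, and 19 further lists lay inside. In the authors' deposited table for 1 mM, 519 probe sets had a change of at least 2-fold, 449 higher and 70 lower.

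**Figure D1:**
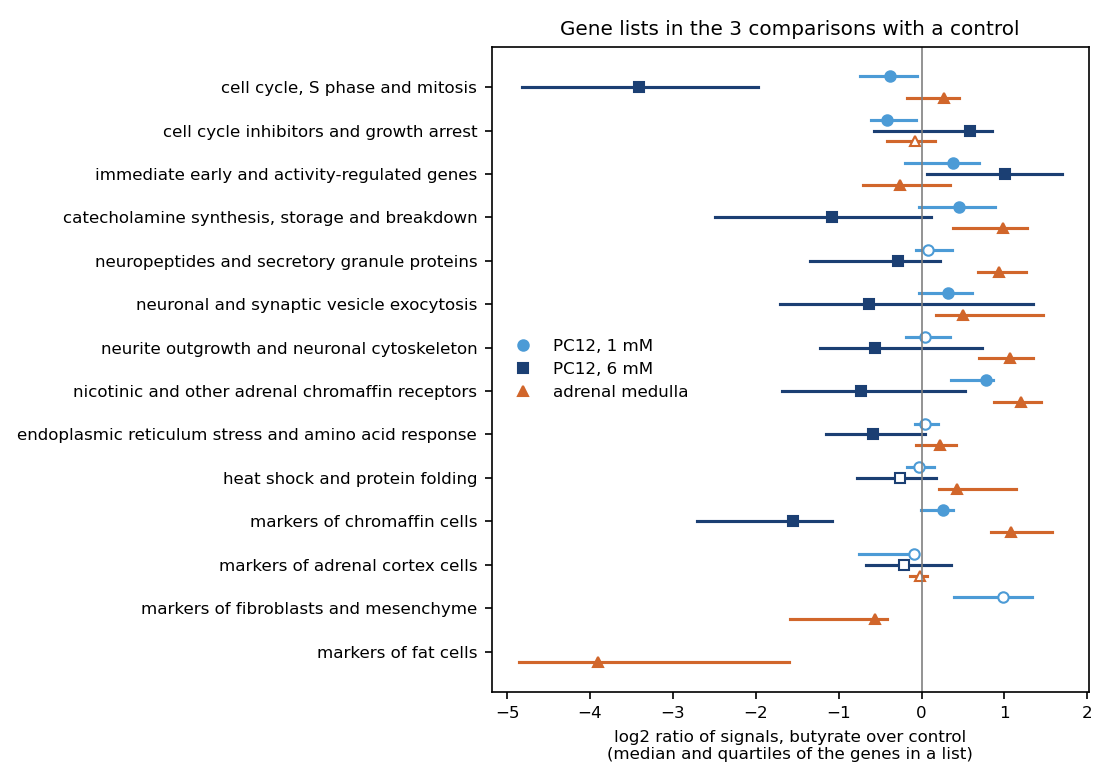
Median log2 ratio of butyrate over control (horizontal axis) of the genes in 14 lists (vertical axis) for PC12 cells at 1 mM (circles), PC12 cells at 6 mM (squares) and the adrenal medulla (triangles), with bars for the lower and upper quartiles of the genes. Filled symbols lie outside the central 95% of random lists and open ones inside, a list with fewer than 3 measured genes has no symbol, and the cell cycle list sits at -3.41 at 6 mM while the chromaffin markers sit at -1.55 at 6 mM and at 1.08 in the adrenal medulla.

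The doses were compared directly and through their calls against the shared control. From 1 mM to 6 mM, 1948 of 19815 probe sets were higher and 2222 were lower. The lowest genes were again Pclaf, at least 116-fold, and Slc18a1, at least 106-fold. Mab21l1 was 79.2-fold lower and Gpnmb, a glycoprotein of melanosomes and macrophages, 30.6-fold lower. The replication and mitosis genes Nuf2 and Mcm5 were 32.7-fold and 27.2-fold lower. Among the highest were Sgk1, a serum- and glucocorticoid-regulated kinase, 15.5-fold, Zcchc12 at least 15.2-fold, Nppb, the brain natriuretic peptide precursor, at least 14.8-fold, H4f3 14.0-fold and Alcam, a cell adhesion gene, 13.5-fold. The cell cycle list had 52 of 58 genes lower with a median of -2.80, the chromaffin markers 11 of 14 with -2.12, catecholamine genes 7 of 12 with -1.79, receptors 5 of 9 with -1.27 and exocytosis genes 11 of 22 with -0.93. Endoplasmic reticulum stress, neurite, heat shock and neuropeptide genes were also below the random lists, with medians of -0.58, -0.32, -0.31 and -0.21. Immediate early genes, at 0.64, and cell cycle inhibitors, at 0.69, were above them. Markers of Schwann cells and of fibroblasts, with 5 and 3 measured genes, had medians of -1.04 and -1.83, the latter -0.18 with dim signals floored. Of the 13 lists apart, 5 were apart under every alternative run, and with Present on both arrays the catecholamine, immediate early and Schwann cell lists moved inside. The neuropeptide, neurite and heat shock lists did so against unmatched random lists, and the cell cycle inhibitors and fibroblast markers without the detection filter.

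Among 18876 probe sets detected in both dose comparisons, 340 were higher at both doses and 92 were lower at both. Independent lists of these sizes would share 54.5 and 29.1. Simulated doses with no effect against the same control array shared 60.6 and 60.5 on average, at most 83 and 82. The simulation called only probe sets Present in control cells, whereas the 340 include others. Its lists averaged 205 higher calls, against 1874 at 6 mM, so its shared counts in any direction are not expected values for the observed ones. Part of the excess may come from the shared control array, whose noise the simulation estimates for probe sets Present there. Another 47 probe sets were higher at 1 mM and lower at 6 mM, and 9 the reverse, where independent lists would give 67.5 and 23.5 and the simulation 3.04 and 2.84. The first set named 28 genes. Ccnd1 read 1826, 5817 and 493.9 at 0, 1 and 6 mM, Ddc 961.7, 3394 and 302.3, and Gap43, a growth cone protein, 563.1, 1893 and 237.3. Hmox1, Crem, Apoc1, Hsd11b1 and Gpnmb belonged to it too. Not all measures of these genes were lower at 6 mM by the size rule: another probe set of Ddc gave -0.24, those of Crem ranged from -3.41 to 0.24, and the authors' deposited table gave Hmox1 and Crem -0.9. Npy read 181.9, 464.8 and 852.7, higher at each dose.

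In the adrenal medulla, most chromaffin markers were higher in butyrate-treated rats, and the lists of catecholamine, neuropeptide, neurite and receptor genes lay above the random lists. Most fat cell markers were lower, and so were 4 of 29 immediate early genes. Of 20984 probe sets Present on at least 1 array, 1303 were higher and 801 were lower, together 10.0%. The fat cell markers had a median of -3.90, or -2.31 floored, with 6 of 8 lower, the fibroblast markers -0.56 with 3 of 11 lower, and the adrenal cortex markers -0.01 with 3 lower and 1 higher of 16.

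Of 16 chromaffin markers, 11 were higher and none was lower, with a median of 1.08 above all random lists, on arrays where the fat cell markers had -3.90. Pnmt read 6402 in control and 17835 in treated rats, 2.79-fold higher, and Th 10088 and 20522, 2.03-fold higher, again with a high signal whose ratio may be compressed. Dbh was 2.03-fold higher, Slc18a1 3.02-fold and Phox2a, a transcription factor of noradrenergic cells, 3.19-fold. Of 14 catecholamine genes, 7 were higher and none was lower, with a median of 0.99, among them Gch1, which makes the cofactor of Th, 3.16-fold, and Ddc 2.54-fold. Of 22 neuropeptide and granule genes, 11 were higher and none was lower, with a median of 0.94. Vgf, a neuropeptide precursor, was 6.41-fold higher, Penk at least 4.27-fold, the granule gene Scg3 3.19-fold, the prohormone convertase gene Pcsk2 at least 3.25-fold and Npy 2.23-fold. Chga read 10400 in control and 16386 in treated rats, below the size rule at a log2 ratio of 0.66. Of 23 exocytosis genes, 8 were higher and none was lower, with a median of 0.50, including Rab3c and Syt4 at 3.83-fold and 3.81-fold and Snap25, a membrane fusion protein, at 3.44-fold.

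Neurite and cytoskeleton genes had a median of 1.07 with 10 of 19 higher and none lower, led by the microtubule protein gene Mapt, 3.41-fold, and by Uchl1, 3.00-fold, beside the fibroblast median of -0.56. Receptors had a median of 1.20 with 5 of 9 higher, including Npy1r at 2.88-fold, Adora2a at least 2.77-fold and Chrna3 at 2.72-fold, though another probe set of Adora2a gave -0.39. Voltage-gated ion channels had a median of 0.74 with 5 of 14 higher, including Scn3b, a sodium channel subunit, at 4.44-fold. Heat shock genes had a median of 0.43 with 5 of 16 higher, led by Hspb8 at 3.73-fold and the inducible chaperone gene Hspa1a at 2.63-fold. Genes of cAMP signalling had 0.38 with 7 of 29 higher and 2 lower, and Crem was 3.03-fold higher, with 0.02 to 2.68 on its other probe sets. Cholesterol genes had 0.43 with 1 of 21 higher, Idi1 at 2.45-fold. Transport of short-chain fatty acids had 0.94 with 2 of 5 higher, Emb, a partner of monocarboxylate transporters, at 2.37-fold and Slc16a3 at 2.26-fold, the latter with 0.5 and no change call in the authors' deposited table. Cell cycle genes had 0.28 with 5 of 50 higher and 1 lower. Mki67 was 2.34-fold higher at 289.3, while Ccnd1 was 2.46-fold lower, with -0.97 and -0.57 on its other probe sets, and Cdkn1a was 1.49-fold higher, below the size rule. Endoplasmic reticulum stress genes had 0.22 with 1 higher and 1 lower of 29, and autism-associated genes had 0.22 with 2 of 16 higher. Histone genes outside S phase lay just inside the random lists at percentile 97.2, with a median of 0.29 and 1 of 8 higher.

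Lower in treated rats were Car3, a carbonic anhydrase abundant in fat and muscle, at least 56.1-fold, the fatty acid binding protein gene Fabp4 at least 17.4-fold, the lipogenic gene Thrsp at least 15.1-fold, Pck1 13.1-fold, Ucp1, the uncoupling protein of brown fat, at least 11.4-fold, and Adipoq, the fat cell hormone adiponectin, at least 6.53-fold. Vsnl1, Wnt4 and the angiotensin receptor gene Agtr1b, which are expressed in the aldosterone-making outer zone of the cortex, were 15.1-fold, 12.5-fold and 8.72-fold lower, and Dab2 was 2.80-fold lower. No list of that zone was fixed, and the adrenal cortex list lay inside the random lists. Nr0b1, a cortical nuclear receptor, was 3.23-fold lower, whereas the lipoprotein receptor gene Scarb1 was 2.92-fold higher. Star, which carries cholesterol to the steroid enzymes, read 23123 and 23439, near the top of the range of the arrays, where ratios may be compressed. The fibroblast markers Postn and Lum were at least 6.70-fold and 4.99-fold lower, Smoc2 was at least 8.33-fold lower and Mia 15.4-fold lower. Of 29 immediate early genes, 4 were lower and 2 higher, with a median of -0.26. Fos read 2125 in control and 173.3 in treated rats, 12.3-fold lower, Junb was 8.23-fold lower, and Dusp1, a phosphatase of early signalling, 4.35-fold lower. Glucocorticoid-induced genes had a median of -0.54, with 2 of 16 lower and 1 higher, Fkbp5 at 2.35-fold. Fatty acid oxidation genes had -0.43 with 2 of 34 lower and 2 higher.

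By floored ratio, the highest genes in the adrenal medulla included Iqub, the zinc finger gene Giot1 and the cyclic nucleotide phosphodiesterase gene Pde10a. Without flooring they were 35.0-fold, 10.7-fold and 7.94-fold higher. Some genes with a dim control signal had larger unfloored ratios than Giot1, such as Tnnt2, at 148.0 against 5.8. Slc6a17, a vesicular amino acid transporter of neurons, was 5.99-fold higher, Eaf2 5.89-fold, the kinase gene Rps6ka6 5.72-fold, Cwc25 5.64-fold, Zfp347 5.59-fold, Scx 5.30-fold and Cox4i2 5.02-fold. Ell2, an elongation factor of RNA polymerase, was 5.61-fold higher on its brighter probe set, but another probe set gave -0.01 on the log2 scale. Markers of endothelial cells, white blood cells and Schwann cells lay inside the random lists, with medians of -0.22, 0.11 and 0.29. Of the 19 lists that stood apart, 16 did so under every alternative run, and 14 lay inside. With Present on both arrays, the fat cell, cAMP and autism-associated lists moved inside. In the authors' deposited table for the adrenal medulla, 1634 probe sets had a change of at least 2-fold, 1061 higher and 573 lower with butyrate.

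**Figure D2:**
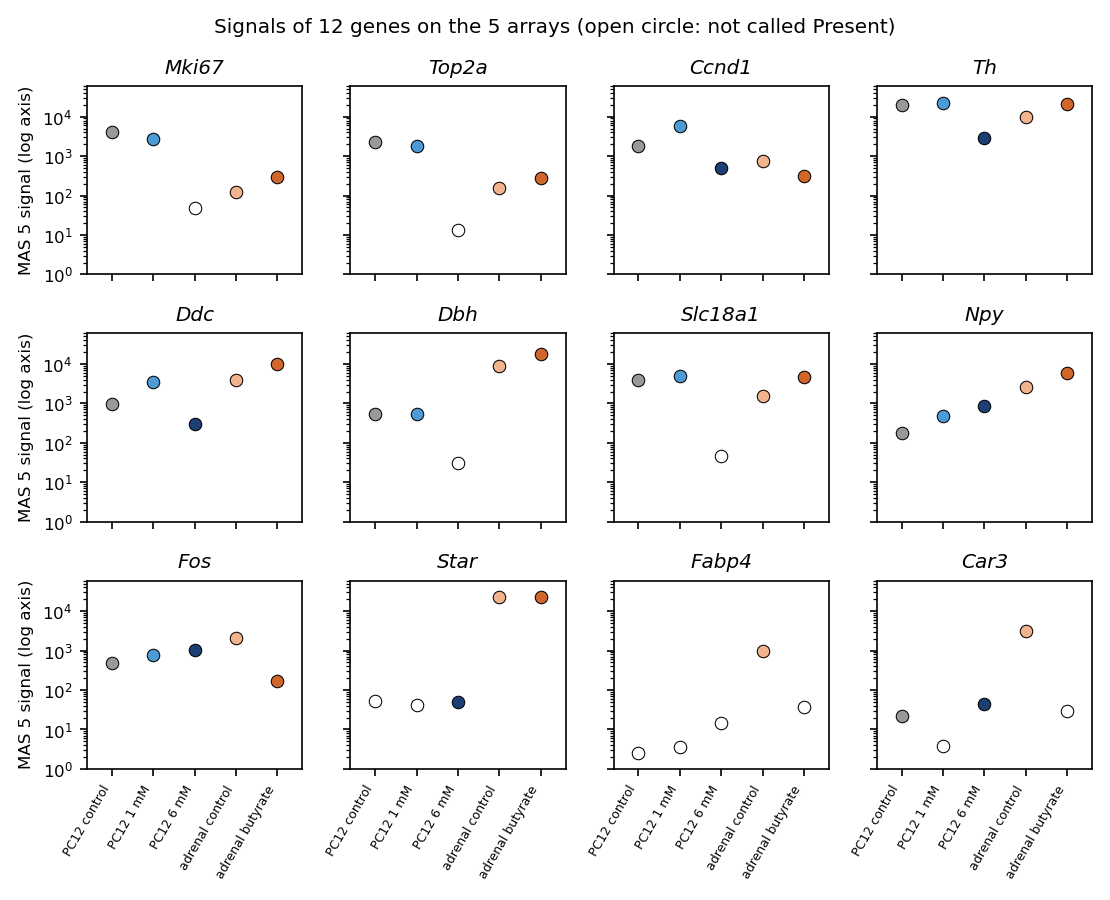
Signals of 12 genes on the 5 arrays on a log axis, 1 point per array and group, with an open circle where the probe set was not called Present. Mki67 and Top2a lie lowest at 6 mM, Th, Dbh and Slc18a1 are lower at 6 mM and higher in butyrate-treated adrenal medulla than in their controls, and Car3 and Fabp4 are Present in the control adrenal medulla and not in the treated one.

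Cells at 6 mM and the adrenal medulla, which share no array, were compared over 17910 probe sets detected in both comparisons. Both were higher for 127 probe sets and both lower for 56, close to the 115 and 48.0 that independent lists would share. Opposite directions were more frequent than independence gives, with 300 lower at 6 mM and higher in the adrenal medulla against 107, and 115 higher at 6 mM and lower in the adrenal medulla against 51.5. Independent lists do not allow for which genes PC12 cells express. In the adrenal medulla, 953 genes at least 8-fold brighter in the adrenal arrays than in PC12 control cells had a median of -0.11. The 126 genes at least 8-fold brighter in PC12 control cells had a median of 0.71, which a larger chromaffin share could give. Opposite responses to butyrate are therefore not shown by these counts. The 300 probe sets named 168 genes, Th, Slc18a1, Chrna3, Prph and Scn3b among them. Cells at 1 mM and the adrenal medulla shared 72 higher and 8 lower probe sets, against 29.1 and 4.06, and had 35 and 14 in opposite directions, against 12.5 and 9.44. In all 3 comparisons with a control, 19 genes were higher, Npy, Gpx3 and Rab3b among them, and 1 gene was lower, Tmem200a, which was named after its values were seen. Its PC12 signals of 19.0, 1.4 and 1.0 at 0, 1 and 6 mM all lay below the background floors, so its calls in PC12 cells do not hold with floored signals. The same limit applies to some of the 19 higher genes, for example Fbxo39 and Tram1l1 at 1 mM and Fbxo39 and Zmynd10 in the adrenal medulla. How many genes would be shared by chance was not computed, and both PC12 comparisons use the same control array.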

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

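Every test in this part except that of chromaffin cell share was chosen after the result was seen. The results below had opposite directions in 2 comparisons, and these differences were not tested, since each group had 1 array. All values are log2 ratios of butyrate over control.

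Among named genes, 47 were called in opposite directions at 6 mM in PC12 cells and in the adrenal medulla. Values are given for the 16 that were fixed beforehand or that the naming rule picked in both comparisons. The catecholamine genes Th (-2.82 and 1.02), Dbh (-4.12 and 1.02) and Slc18a1 (-6.37 and 1.593) were lower in cells and higher in the gland. So were the receptor genes Adora2a (-3.48 and 1.47), Chrna3 (-1.60 and 1.44) and Adcyap1r1 (-1.69 and 1.33), and the channel genes Scn3b (-1.31 and 2.15) and Kcnma1 (-1.53 and 1.29). The chaperone genes Hspa1a (-1.14 and 1.40) and Hspb8 (-1.11 and 1.90), the transporter genes Slc16a3 (-1.16 and 1.17) and Slc2a3 (-1.22 and 1.39) and the histone variant gene Macroh2a2 (-1.88 and 1.35) did the same. Higher in cells and lower in the gland were RT1-Ba (2.82 and -1.05), RT1-Bb (2.63 and -1.71) and Tp53inp1 (2.03 and -1.38). Where the dimmer array was called Absent, only a bound on the fold is given. Not all such signals lay near background: Adcyap1r1 read 250.9 at 6 mM and 498.3 in the control gland, above the floors of 42.9 and 58.6. At 6 mM this was at least 12.6-fold for Dbh, 82.6-fold for Slc18a1, 3.22-fold for Adcyap1r1, 6.81-fold for RT1-Ba, 4.57-fold for RT1-Bb and 4.09-fold for Tp53inp1. In the gland it was at least 2.77-fold for Adora2a, 2.52-fold for Adcyap1r1 and 2.61-fold for Tp53inp1.

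Other measures differed for some of these genes. In the gland, the authors' deposited table gave no change call to Macroh2a2 (0.1) and Slc16a3 (0.5), and other probe sets gave -0.39 for Adora2a, 1.00 for RT1-Ba and -0.47 for RT1-Bb. At 6 mM, other probe sets gave -0.51 and -0.45 for Adcyap1r1, -0.63 for Kcnma1, -0.89 for Hspb8, -0.87 for Slc2a3 and 0.72 for RT1-Bb, all under the size rule. So were 0.75 for Kcnma1 and 0.84 for 1 probe set of Adcyap1r1 in the gland. Between the doses, 12 named genes were called in opposite directions, and Ccnd1, the only 1 of them fixed beforehand or picked at both doses, was at 1.67 for 1 mM and -1.89 for 6 mM.

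Among gene lists, medians lay on opposite sides of the random lists at 6 mM and in the adrenal medulla for catecholamine genes (-1.08 and 0.99), neuropeptides and granules (-0.28 and 0.94), exocytosis (-0.64 and 0.50), neurite genes (-0.57 and 1.07), receptors (-0.73 and 1.20), cell cycle (-3.41 and 0.28), immediate early genes (1.01 and -0.26), endoplasmic reticulum stress (-0.59 and 0.22) and chromaffin markers (-1.55 and 1.08). They did so between 1 mM and 6 mM for catecholamine genes (0.45 and -1.08), exocytosis (0.32 and -0.64), receptors (0.77 and -0.73), cell cycle inhibitors (-0.42 and 0.58) and chromaffin markers (0.26 and -1.55). These lists are not separate results, since some share genes: Th, Dbh, Slc18a1, Chga and Snap25 are chromaffin markers and also belong to another list. At 6 mM, the catecholamine, neuropeptide, exocytosis and receptor medians each moved inside the random lists under 1 alternative.

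In the adrenal medulla, most chromaffin markers were higher and most fat cell markers lower. Genes of the outer zone of the cortex were lower too, Vsnl1, Wnt4 and Agtr1b among them, though no list of that zone was fixed. The scaling of the arrays is argued against, since the chromaffin median was 1.07 after quantile normalization. A larger share of chromaffin cells in the butyrate pool may account for part of it: 126 genes outside the lists that were at least 8-fold brighter in PC12 control cells than in the adrenal arrays had a median of 0.71, with 109 above 0, where the highest of 1000 matched random sets reached 0.21. The reverse set, 953 genes at least 8-fold brighter in the adrenal arrays, had a median of -0.11. All genes outside the lists had -0.04. Markers of cortex, endothelial, white blood and Schwann cells had medians of -0.01, -0.22, 0.11 and 0.29, inside the random lists. Fibroblast markers had -0.56, below them. Fat tissue carried into the control pool stays open, since the 6 of 8 markers that were at least 2-fold lower are the pattern itself and test nothing. Whether such tissue also lowered the chromaffin share of the control pool was not tested. An effect of butyrate in chromaffin, cortical or fat cells was not tested and stays open, and it could give the same values.

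At 6 mM, most cell cycle genes and chromaffin markers were lower. RNA degradation is argued against, since the ratio of 3' to 5' signals of beta-actin at 6 mM was 1.16 times that in control cells. The scaling of the arrays is argued against too, since the cell cycle median was -3.23 after quantile normalization. An effect of butyrate is an untested biological explanation, and a difference in culture density between the pools stays open as well.

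At 1 mM, more probe sets were higher than lower. A lower background on the control array is argued against as the whole cause, since 78.7% of the calls were higher when Present was required on both arrays. It may account for part. The background floor was 31.4 on the control array and 37.1 at 1 mM, and quantile normalization lowered the share of higher calls from 75.9% to 66.4%. Noise of single probe sets is argued against for 42 of the genes called higher. Of the other probe sets of these 42 genes, 45 of 47, or 95.7%, were also above 0, against 49.3% of all probe sets Present on at least 1 of the arrays. Genes without such another probe set were not covered. Genes called lower were not tested in this way, so this agreement does not tell why higher calls were more frequent. An effect of butyrate was not tested, and a difference between the pooled cultures stays open.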

How the results depend on the processing

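The alternatives below were all chosen before the data were examined. Leaving out a replicate was not possible with 1 array per group, and the authors' log ratio and change call were not run for 6 against 1 mM, for which no such table was used. No paired analysis was possible because each group had 1 array. Counts stayed within 1.5 times under the authors' deposited log ratio, quantile normalization, centring and the series-wide table. Of 1106 list percentiles recomputed, 1048 kept their place relative to the random lists, 34 moved inside, 24 moved outside and 0 changed sides. Of 4367 recomputed ratios of named genes, 3979 kept their call or stayed without one, and 377 lost their call without changing to the opposite direction. Most lost calls came with Present on both arrays (125 of 420) or the 3-fold threshold (158 of 420). Among ratios called as deposited, only 2 changed direction, both with floored signals, which construction explains, since both signals were below the floors of their arrays: Cyp11b1 at 1 mM (0.24) and Emcn between doses (0.21). Changes of direction in ratios that were not called were not counted.

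Counts are given as higher, then lower, and they moved because each setting admits fewer or more probe sets by construction. With Present on both arrays, 6 mM gave 1592 higher, 1 mM 358 and 97, 6 against 1 mM 1281 higher and the adrenal medulla 502 lower, and 81 probe sets moved the same way at 6 mM and in the adrenal medulla and 202 at both doses. Without the detection filter, the counts were 6158 and 4171 at 6 mM, 3906 and 2285 at 1 mM, 4858 and 4467 between doses, 3067 and 2891 in the adrenal medulla, and overlaps of 1271 and 3334. At 1.5-fold they were 4966 and 4133, 1824 and 1117, 4431 and 3925, 2643 and 2467, with overlaps of 747 and 1478. At 3-fold they were 1105 and 1149, 275 and 68, 719 and 1128, 345 and 244, with overlaps of 30 and 136. Requiring the authors' change call left 458 and 72 at 1 mM and overlaps of 117 and 259, and flooring left 111 lower at 1 mM. The share of higher calls at 6 mM was 52.2%, 47.6% after quantile normalization, 47.7% after centring and 48.7% with Present on both arrays (1592 and 1678), so which direction was larger depended on the scaling, on the filter and on the threshold, since lower calls were also more at 3-fold. At 1 mM it was 75.9% and 66.4% after quantile normalization. The cause of these shifts was not tested.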

Other observations

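The tests of explanations in this closing section are given with the results they concern, and none was added here. Further gene groups at 6 mM held called members although their lists lay inside the random lists. Of all 10320 genes measured at 6 mM, 12.9% were higher and 12.5% were lower. Called members alone therefore do not set a group apart. Of 16 interferon and antiviral genes, 6 were higher and 2 lower, with a median of 0.41. Ifitm1, an antiviral membrane protein, was at least 7.36-fold higher at 6 mM and at least 4.67-fold at 1 mM, and Bst2, which tethers viruses, was 2.69-fold and 3.61-fold higher, whereas the immunoproteasome gene Psmb8 was 6.09-fold lower at 6 mM. At 1 mM, 5 of 14 such genes were higher and none was lower, with a median of 0.17. Of 29 fatty acid oxidation genes, 5 were higher and 2 lower at 6 mM, with a median of 0.26. Hadh was 4.80-fold, Decr1 3.54-fold and Acaa2 2.98-fold higher, all enzymes of mitochondrial beta-oxidation, with 0.15 on the log2 scale on another probe set of Acaa2. Of 21 cholesterol genes, 4 were lower and 1 was higher at 6 mM, with Acat2 3.20-fold and Cyp51 2.68-fold lower and Hsd17b7 3.15-fold higher.

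Among histone deacetylases, acetyltransferases and readers, 3 were higher and 1 was lower of 29 at 6 mM, with a median of -0.22. Hdac1, a class I deacetylase, was 2.36-fold higher, Sirt7 2.65-fold and the coactivator gene Ncoa3 3.06-fold, while the acetyltransferase gene Kat2b was 5.00-fold lower. Kat2b was 2.04-fold lower in the adrenal medulla too. Among histone genes outside S phase, 2 of 8 were higher at 6 mM, and H2ac25 was 4.89-fold higher, with Macroh2a2 3.67-fold lower. The 25 measured genes of cytosolic ribosomal proteins had no call at 6 mM, with a median of 0.37, and 1 of 37 oxidative phosphorylation genes was lower, with a median of 0.25.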
